A study of Fukomys damarensis with 16 samples.

How the data were processed

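Messenger RNA was profiled in 16 libraries of the Damaraland mole-rat, Fukomys damarensis, a burrowing rodent whose colonies hold breeding animals and non-breeding helpers. The labels give each library a tissue, a sex and a breeding status, and no 2 libraries share all of them, so each of the 16 groups holds 1 library. Kidney, liver and brain were each sampled from a breeding male, a breeding female, a non-breeding male and a non-breeding female. Ovary came from a breeding and a non-breeding female, and testis from a breeding and a non-breeding male. The labels give an age of 5 years for the non-breeding males and 3 years for the non-breeding females and none for the breeders, so age and breeding status cannot be separated. Nor can age and sex in the non-breeding libraries. The non-breeding male library is labelled brain, and the other 3 brain libraries are labelled frontal brain. Nothing in the labels says which libraries came from the same animal, or whether a library holds RNA of several animals. P-values therefore measure only the spread between these libraries.

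Per the labels' protocols, RNA was extracted with TRIzol, selected by its poly(A) tail, copied from random hexamers, sheared, size selected, amplified and read from both ends on an Illumina instrument. The labels mention no marking of strand. The authors deposited 1 table of RPKM values (reads per kilobase of gene model per 1e6 reads) with a row per gene and a column per library. The submitters' processing notes name TopHat 1.3.1, a spliced aligner. The genome build, the annotation and the counting tool are not given in the sources used here. All 16 columns were used. The table holds 21082 gene identifiers. None of them (0 of 21082) was found among the names, locus tags, synonyms or accessions of the 33132 genes in the RefSeq table of assembly DMR_v1.0_HiC. The files thus do not pair identifiers with gene names, and no more than 2 identifiers per direction of a comparison are printed. For the same reason the 49 gene lists and the markers of cell types fixed before the data were examined could not be used, and their set tests (limma's camera and fry) were not run.

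The RPKM values are quotients of whole numbers, which allowed the reads behind them to be recovered. For each gene the length, and for each library the divisor, were sought that turn all values into whole reads. A whole-read solution was found for 100% of the 21082 genes, with 100% of the values above 0 within 1e-06 of a whole read or 1e-11 of their size, and the values rebuilt from it deviated by at most 3e-14 of their size. On simulated RPKM of 5734 genes, with lengths drawn as multiples of 3, the step returned all 16 divisors and 100% of the read numbers. The unit of length was set at 3 bases, so multiples of 3 are by construction. The median was 1056 bases, and the lengths are taken as coding lengths. Under this unit all divisors came within 6.7e-08 of a whole number. A unit of a single base would make each divisor a larger multiple of 3. It would lower the ratio of reads to divisor to the same degree in every library. Divisors lay between 13274642 and 38953023 and reads on genes between 15393003 and 27593857.

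In kidney, brain, ovary and testis the reads on genes came to 0.665 to 0.945 of the divisor, and in liver to 1.55 to 1.97 of it. The deposited RPKM of a liver library consequently add up to 1172850 to 1536310, against 430941 to 681080 in the other libraries. Among genes with 1 to 20 reads, the share with an even number was 48.0% to 49.2% in liver and 45.8% to 48.1% elsewhere. The recovery scales down a library whose counts are nearly all even, so this share cannot tell whether a pair added 2 reads. Whether an end or a pair counts as a read stays open. Without the 100 most abundant genes of each library the ratio was still 0.812 to 0.929 in liver against 0.581 to 0.773 in the other tissues. What the divisor counts is not given in the sources used here. Levels in liver are therefore too high relative to the other tissues if reads on genes are taken as the measure, and the counts of genes higher and lower in a tissue are given under both scalings. Other values across tissues use the deposited scaling alone.

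Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Log2 differences are on this scale, which understates changes of low genes. Genes with an RPKM of 1 or more in at least 2 libraries of a fit were tested, 17327 of them in all 16 libraries and 15964 in the 12 kidney, liver and brain libraries. A first fit compared each tissue with the mean of the other 4 and called genes that also differed by at least 1 on the log2 scale. A second fit of the 12 libraries held tissue, breeding status and sex, and so gave differences shared by the 3 tissues, with 7 residual degrees of freedom. A last fit gave status and sex their own effect in each tissue, with 3 residual degrees of freedom, and tested whether the breeding effect differed between tissues. Each tissue then has 2 breeding and 2 non-breeding libraries, of different sexes. The tissues share the estimate of a gene's spread, so an SE or p-value for liver also rests on brain and kidney. Ovary and testis have 1 library per status, so only log2 ratios are given there and nothing was tested. Genes at 1 RPKM or more in either library were counted. In each tissue except the gonads, genes that differed by 2-fold or more in both the male and the female pair were also counted.

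The fits were tested on simulated reads with the depths of these libraries and 200 changed genes. Means were those of each tissue, except for brain against the other tissues, where each gene had a single mean over all libraries. Genes of similar level shared their median dispersion, and libraries varied independently. Genes of wider spread and deviations shared by a class were not simulated, so the shares called may be too favourable. For breeding against non-breeding in the 3 tissues together, 74.6% of 2-fold, 98.5% of 4-fold and 97% of 8-fold changes were called among 16030 genes, with 2 unchanged genes called. For breeding against non-breeding in liver alone, the shares were 2.99%, 62.7% and 80.3% among 16016 genes, with 10 unchanged genes called. For the difference between kidney and liver effects they were 0%, 17.9% and 65.2%, with 1 unchanged gene called. For brain against the other tissues they were 34.3%, 98.5% and 100% among 16714 genes, with 1 unchanged gene called. Calls there also needed a log2 difference of at least 1. A 2-fold change falls short of that on this scale, so the share of 34.3% is low in part by construction.

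Genes were to be named by a rule set before the data were examined: the called genes with the largest log2 difference in each direction, and in the gonads the largest log2 ratios among genes at 5 RPKM or more in the higher library. It was applied to identifiers and stopped at 2 per direction. Groups of genes were formed from the libraries themselves, a choice made after the data had been seen: a gene belonged to a tissue if it had 5 RPKM or more in each library of that tissue and a mean at least 8 times that of each other tissue. Their median log2 ratio was placed among the medians of 10000 random lists of equal size matched on mean level in 20 bins. Such a percentile describes the libraries compared and is not a test of status. Correlations are across genes, which are not independent replicates.

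Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, scaling by trimmed means, quantile normalization, limma's array weights, leaving out each library, leaving out the library labelled brain, kidney and liver only, status and sex class as a block, and a 4-fold threshold. The fit without the library labelled brain is also among those leaving out each library. Tallies of alternatives for a gene in the breeding and sex fits count it in both places. Scaling to the reads on genes, limma's voom on the recovered reads, and the fits without the breeding female liver and kidney were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work. Limits set by a count of 0 use 3 reads and cover counting error only, since reads of amplified libraries are not independent molecules.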

Results

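The study compared breeding and non-breeding mole-rats of both sexes across 5 tissues. Kidney, liver and brain have 1 library for each combination of status and sex, and ovary and testis 1 for each status. The 4 liver libraries held 23857020 to 27593857 reads on genes, the brain libraries 15393003 to 17541246, the kidney libraries 15634095 to 19534775, the ovary libraries 23295227 (breeding) and 17641918, and the testis libraries 18555319 (breeding) and 26730187. For genes with 100 or more reads in a pair, the median squared deviation between the 2 ovary libraries was 24.7 times that of counting error, and between the 2 testis libraries 21.3 times. For pairs of libraries within brain, kidney or liver it was 12.5 to 47.7 times. No replicate libraries of a group exist, and the error of a value below is the spread between libraries of a tissue or a status.

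**Figure D1:**
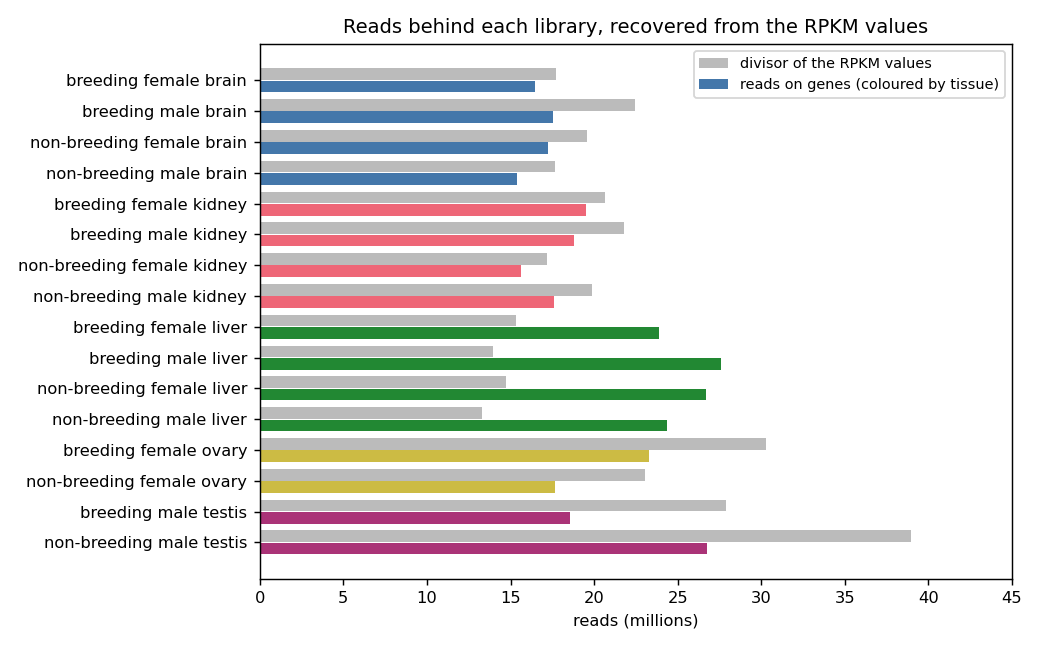
Reads of the 16 libraries (1e6 reads), recovered from the deposited RPKM values: the divisor of the values (grey) and the reads on genes (coloured by tissue). The coloured bar is longer than the grey bar in the 4 liver libraries, where it reaches 1.55 to 1.97 times the divisor, and shorter in the other 12.

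The testis expressed the most genes and the liver the fewest. An RPKM of 1 or more was reached by 14925 and 15077 genes in the testis libraries, 14130 ± 77.2 in brain (SD, n = 4), 13380 ± 116 in kidney (SD, n = 4), 13288 and 13796 in ovary and 12710 ± 286 in liver (SD, n = 4). The order of testis and liver held when every library was thinned to the same number of reads on genes, with at least 5 reads in 17131 and 17170 genes in testis and in 13272 to 14109 in liver. In all 16 libraries 10139 genes were at 1 RPKM or more. The testis also had the most genes of its own: 193 genes were at 1 RPKM or more in both testis libraries and under 0.1 RPKM in each of the other 14, against 25 such genes in brain, 6 in ovary, 5 in kidney and 3 in liver. Liver transcripts were the most unevenly spread. The most abundant gene took 11.1% to 16.8% of the reads on genes in liver and 0.588% to 3.16% in the other tissues, and the 100 most abundant took 51.0% ± 2.34 (SD, n = 4) in liver against 16.7% ± 0.208 (SD, n = 4) in brain.

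Libraries grouped by tissue ahead of sex and status. Pearson correlations of log2 values across the 17327 genes tested were 0.966 to 0.984 within brain, 0.960 to 0.984 within kidney, 0.956 to 0.983 within liver, 0.965 between the ovaries and 0.979 between the testes. Between tissues they ran from 0.452 to 0.801, with kidney and liver nearest to each other (median 0.774) and the ovary nearest to kidney (median 0.764). The first 4 principal components held 47.5%, 20.7%, 17.1% and 8.46% of the variance and the fifth 1.46%.

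**Figure D2:**
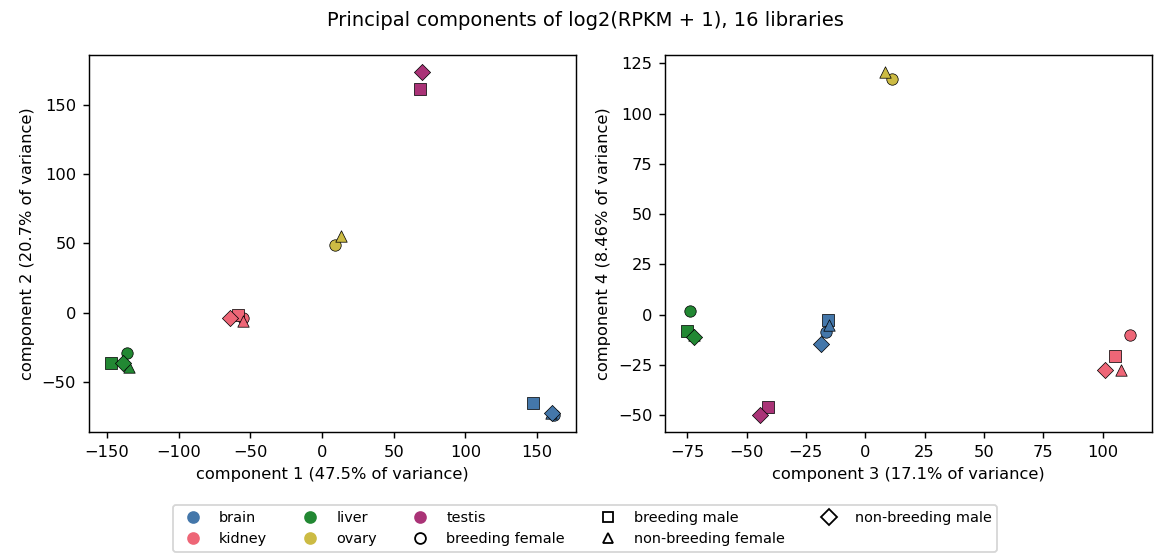
Scores of the 16 libraries on the first 4 principal components of log2(RPKM + 1), coloured by tissue, with a symbol for each status and sex. Libraries of a tissue lie together on both panels, and component 4, with 8.46% of the variance, sets the 2 ovary libraries apart.

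Each tissue was compared with the mean of the other 4. The gene with the largest difference in liver, DMR_10289, had a mean of 158300 RPKM there (SD 40670, n = 4) against 137.1 in kidney (SD 194, n = 4) and 41.6 in brain (SD 14.9, n = 4), a log2 difference of 13.3 (SE 0.57, limma adjusted p = 2.72e-11). In kidney DMR_07783 stood at 6552 RPKM (SD 2000, n = 4) and at most 8.37 in any other library (log2 difference 11.1, SE 0.284, limma adjusted p = 1.26e-13). In brain DMR_17735 stood at 1380 RPKM (SD 267.6, n = 4) and at most 2.39 elsewhere (log2 difference 9.60, SE 0.219, limma adjusted p = 1.2e-14). DMR_17300 led in ovary, with 3622 and 6912 RPKM there, 226.4 and 431.3 in testis and at most 1.40 elsewhere (log2 difference 9.75, SE 0.296, limma adjusted p = 7.62e-12). DMR_01561 led in testis, with 1217 and 1689 RPKM there, 0 in both ovary libraries and at most 0.507 elsewhere (log2 difference 10.3, SE 0.18, limma adjusted p = 9.87e-16).

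In all, 11414 of the genes tested (65.9%) were called higher in at least 1 tissue by limma, and 8955 of them in exactly 1. Brain had 3464 genes higher and 3538 lower, kidney 2153 and 2692, liver 2661 and 4118, ovary 1913 and 2710, and testis 3799 and 3429. With the deposited scaling, kidney and liver shared 720 of their higher genes, where independent lists of these sizes would share 330.6. Every other pair shared fewer than independent lists would, such as liver and testis with 103 against 583.4. These comparisons share libraries, since each tissue is part of the mean set against the others. A gene high in a tissue raises the mean set against every other tissue, so low sharing is in part built in. The counts of higher and lower genes rest on the scaling. With each library scaled to its reads on genes, the median gene moved by -0.80 (log2) in liver, 0.47 in testis and 0.28 in ovary. Liver then had 1229 genes higher and 9058 lower (11.9% of calls higher, against 39.3% as deposited). Testis had 5549 and 2071 (72.8% against 52.6%) and ovary 2984 and 2300 (56.5% against 41.4%). Brain turned to a majority higher, with 3765 and 3349 (52.9% against 49.5%), and kidney had 2294 and 2807 (45% against 44.4%). With voom on the recovered reads liver had 1459 higher and 10787 lower, testis 6716 and 1958, and ovary 3948 and 2229 (63.9% higher). Quantile normalization turned the majority in testis the other way, with 3640 higher and 4375 lower (45.4% higher). It gave 2790 and 3356 in liver (45.4%) and 2377 and 2493 in ovary (48.8%). The 5 leading genes named above passed the threshold under each of the alternatives run.

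**Figure D3:**
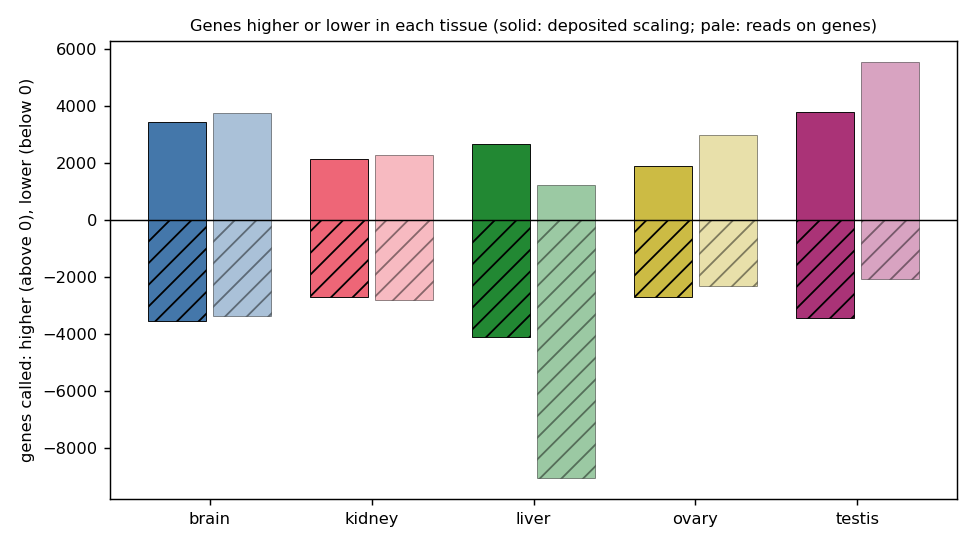
Genes called higher (plain bars above 0) and lower (hatched bars below 0) in each tissue than in the mean of the other 4, by limma at adjusted p 0.05 and a log2 difference of at least 1. Solid bars use the deposited scaling and pale bars the reads on genes; liver goes from 2661 higher and 4118 lower to 1229 and 9058.

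Breeding and non-breeding libraries of kidney, liver and brain were compared together, with tissue and sex in the model. Of 15964 genes, 4 passed the threshold of limma, 3 higher and 1 lower in breeding libraries, and 2161 had an unadjusted p under 0.05. DMR_21816 rose by 2.19 on the log2 scale (SE 0.215, limma adjusted p = 0.00273), from 3.10 RPKM (SD 1.64, n = 6) in non-breeding to 17.3 (SD 6.56, n = 6) in breeding libraries. DMR_15844, an abundant transcript with a short coding length of 348 bases, rose by 1.82 (SE 0.163, limma adjusted p = 0.0016), from 210.2 RPKM (SD 175, n = 6) to 689.6 (SD 515, n = 6). The remaining gene that rose went from 12.8 RPKM (SD 1.92, n = 6) to 38.0 (SD 6.82, n = 6), a log2 difference of 1.48 (SE 0.106, limma adjusted p = 0.000285). DMR_16626 had a log2 difference of -0.93 (SE 0.117, limma adjusted p = 0.0252), with 7.18 RPKM (SD 0.672, n = 6) in breeding and 14.8 (SD 3.42, n = 6) in non-breeding libraries. All 4 genes went the same way in 6 of 6 pairs of libraries matched for tissue and sex. DMR_16626 passed the threshold under 9 of 23 alternatives, with adjusted p from 0.00682 to 0.255. Among the 14 alternatives in which it missed were voom, scaling to reads on genes, and kidney and liver only. Others were the fits without any 1 of the 4 livers, the non-breeding brains, the breeding kidneys or the non-breeding female kidney. DMR_21816 missed it with kidney and liver only (adjusted p = 0.255, range over the alternatives 0.000274 to 0.255), and the other 2 genes passed it under all 23. The number of calls was 57 without the breeding female brain and 12 with status and sex class as a random block. The estimated correlation of libraries of a class was -0.0981 there, and a negative value narrows the error of this comparison.

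The ovary and testis libraries were not part of that fit. DMR_21816 stood at 12.1 RPKM in the breeding and 1.53 in the non-breeding ovary, and at 24.1 and 4.45 in the testes. DMR_15844 stood at 848 and 406 RPKM in the ovaries and at 242 and 98.6 in the testes. DMR_16626 stood at 5.27 and 16.4 RPKM in the ovaries and at 23.4 and 25.0 in the testes.

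**Figure D4:**
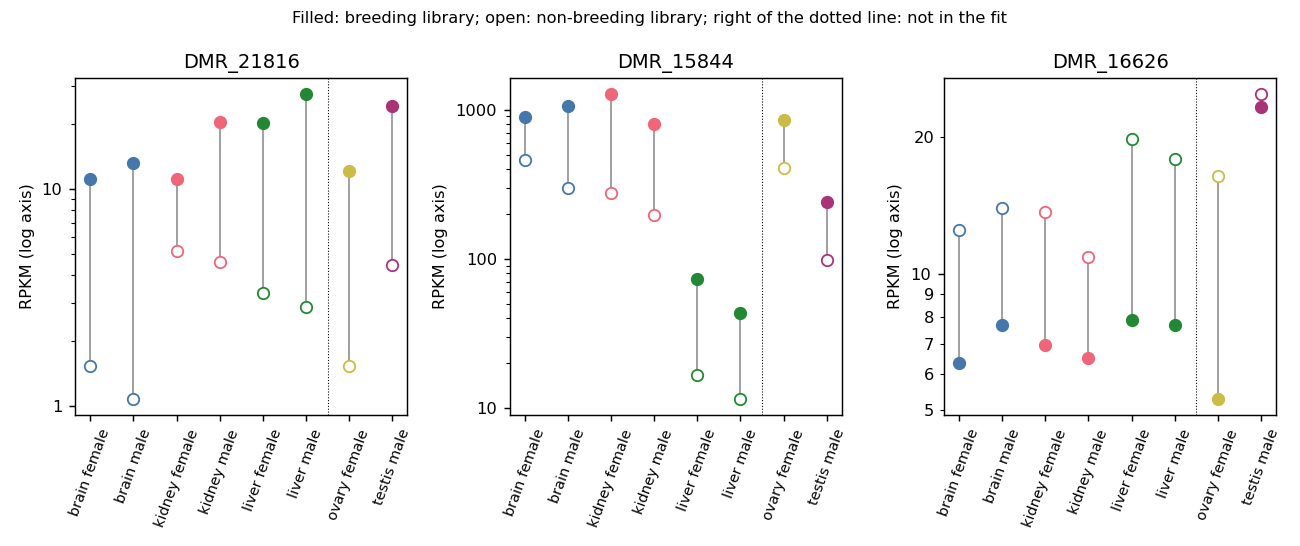
RPKM on log axes of 3 of the 4 genes called between breeding (filled) and non-breeding (open) libraries, for each tissue and sex. Ovary and testis, right of the dotted line, were not in the fit; DMR_21816 is higher and DMR_16626 lower in the breeding library of all 8 pairs, and DMR_15844 higher in all 8.

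Within single tissues, liver alone gave calls for breeding status. DMR_05374 stood at 29.6 and 42.6 RPKM (45 and 59 reads) in the breeding livers. In the non-breeding livers it stood at 0.686 and 0.761 RPKM, from 1 read each (log2 difference 4.41, SE 0.223, limma adjusted p = 0.00231). It was listed at 0 in all kidney and brain libraries. These add no spread to the shared estimate, so the p-value does not measure the spread in liver alone. DMR_18392 had a log2 difference of -3.83 (SE 0.291, limma adjusted p = 0.0205), with 0.541 and 0.935 RPKM in the breeding and 21.2 and 26.0 in the non-breeding livers. DMR_05374 passed the threshold under 8 of 19 alternatives and DMR_18392 under 6 of 21. DMR_18392 missed it after scaling to reads on genes (adjusted p = 0.0596) and with kidney and liver only (0.0504), within a range of 0.0117 to 0.548 over the alternatives. It was also lower in the breeding brains (0.976 and 1.24 against 8.73 and 13.0 RPKM), kidneys (1.22 and 2.49 against 3.65 and 4.09) and ovary (4.54 against 16.4), and higher in the breeding testis (7.59 against 4.97). No gene was called in liver when any 1 of the 8 brain and kidney libraries was left out, and 231 and 247 were called without the breeding male and the non-breeding male liver. Limma called 0 genes in brain, where 271 had an unadjusted p under 0.05 and voom called 0, and 0 genes in kidney, where 1177 had an unadjusted p under 0.05 and voom called 1. In liver 1391 genes had an unadjusted p under 0.05. The breeding effect of DMR_05374 differed between liver and kidney and between liver and brain (both limma adjusted p = 0.0267), the call for 1 gene in each comparison, lost with voom, with quantile normalization, with a pseudocount of 0.1 and without any 1 of the brain and kidney libraries or the non-breeding female liver. Without a breeding liver the gene was not tested, being at 1 RPKM or more in 1 library alone. Between brain and kidney limma called 0 genes, 361 had an unadjusted p under 0.05, and voom called 0.

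Male and female pairs moved together in part. In kidney 106 genes differed by 2-fold or more in the same direction in both sexes (74 higher and 32 lower in breeding libraries) and 50 in opposite directions. In liver the counts were 122 (82 higher, 40 lower) and 75. In brain 18 genes went the same way (13 higher, 5 lower) and 56 opposite ways. Correlations of the male and female ratios across genes were 0.190 in kidney, 0.155 in liver and -0.288 in brain. Over all 6 pairs of the 3 tissues, 550 genes were higher and 584 lower in every breeding library than in its partner. Going up in all male and down in all female pairs were 248 genes, and the reverse 305. For male over female, 855 genes were higher and 722 lower in all 6 pairs. Independent pairs without any difference would give 498.9 genes for both directions together. The pairs reuse the same classes of status and sex and are not independent.

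Male and female libraries of kidney, liver and brain differed in 78 genes by limma, 53 higher in males and 25 higher in females, with 3100 genes at an unadjusted p under 0.05. By their labels the non-breeding males were 5 and the non-breeding females 3 years old, so age goes with sex there. The genes with the largest rise in males were DMR_09602, at 37.8 RPKM (SD 15.6, n = 6) in males and 0.0112 (SD 0.0274, n = 6) in females, and DMR_09601, at 18.6 RPKM (SD 5.4, n = 6) and 0.0101 (SD 0.0248, n = 6). Their fitted log2 differences were 5.16 (SE 0.196) and 4.23 (SE 0.156), both at a limma adjusted p of 1.44e-07; these differences depend on the pseudocount, as the female values are near 0. The genes with the largest fall were DMR_21567 (log2 difference -1.82, SE 0.26, limma adjusted p = 0.0203) and DMR_14256 (-1.35, SE 0.172, limma adjusted p = 0.0132). DMR_21567 missed the threshold under 9 of 23 alternatives, among them each fit without 1 of the male brains or the breeding female brain, the non-breeding kidneys, the breeding male liver or the non-breeding female liver. DMR_14256 missed it with kidney and liver only and without the non-breeding female kidney. DMR_14256 had 36.9 RPKM (SD 14.9, n = 6) in males and 100 (SD 50.8, n = 6) in females. The number of calls depends on single libraries and settings: it was 749 without the breeding female liver, 9 without the breeding male liver or the non-breeding female kidney, 8 with kidney and liver only, 547 with array weights and 28 after scaling to reads on genes.

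A set of 8 genes was read in males and nearly absent from females. Each had 10 or more reads in all 6 male libraries of kidney, liver and brain and no more than 1% as many reads in the 6 female libraries together. Their reads came to 24232 in the male and 7 in the female libraries. All 8 were also read in both testis libraries, and none had a read in the 2 ovary libraries, a count of 0 that allows up to 3 reads. No gene met the mirror-image criterion for females. All 8 were among the 78 calls, and they were the only genes 2-fold or more higher in males in all 6 pairs. In kidney, liver and brain the criterion fixes this pattern, and the 4 ovary and testis libraries, which it did not use, matched their sex labels.

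Within tissues limma called 8 genes between the sexes in brain, 14 in kidney and 34 in liver, and 7 of the 8 male genes were among the calls in each. The liver had the largest further differences. DMR_12174 stood at 455 and 4460 RPKM in the female and at 1.21 and 47.8 in the male livers (log2 difference -7.10, SE 0.439, limma adjusted p = 0.0026). DMR_02930 stood at 176 and 220 RPKM in the female and at 3.42 and 6.81 in the male livers (log2 difference -5.07, SE 0.352, limma adjusted p = 0.00308). DMR_08805 stood at 714 and 1390 RPKM in the male and at 9.63 and 63.7 in the female livers (log2 difference 5.25, SE 0.606, limma adjusted p = 0.0269). DMR_12174 passed the threshold under 16 of 21 alternatives, DMR_02930 under 12 and DMR_08805 under 6. DMR_08805 missed it after scaling to reads on genes (adjusted p = 0.055) and with kidney and liver only (0.0923), within a range of 0.00309 to 0.489 over the alternatives. Without any 1 of the brain libraries 0 genes were called in liver by limma, and without any 1 of the kidney libraries 4, while 227 and 224 were called without the non-breeding female and the non-breeding male liver. In the full fit 1331 genes in liver had an unadjusted p under 0.05, and voom called 61. Whether the sex effect differed between tissues was not tested.

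In the ovary, 896 of 14109 genes were 2-fold or more higher and 270 lower in the breeding than in the non-breeding library. The highest ratios belonged to DMR_07981, at 1181 RPKM (41437 reads) against 5.95 (159 reads), and DMR_01018, at 903.6 (15444 reads) against 4.46 (58 reads). The lowest ratios belonged to DMR_18421, at 31.9 against 321.4 RPKM, and DMR_20305, at 4.16 against 48.3. The 58 genes of the ovary group had a median log2 ratio of 0.05, at percentile 86.9 of the random lists. Genes of other tissues were higher in the breeding ovary: the median was 0.51 for 106 measured kidney genes, 0.38 for 153 liver genes and 0.29 for 354 brain genes, all above the medians of all 10000 random lists, while it was 0.04 for 267 testis genes (percentile 1.29).

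**Figure D5:**
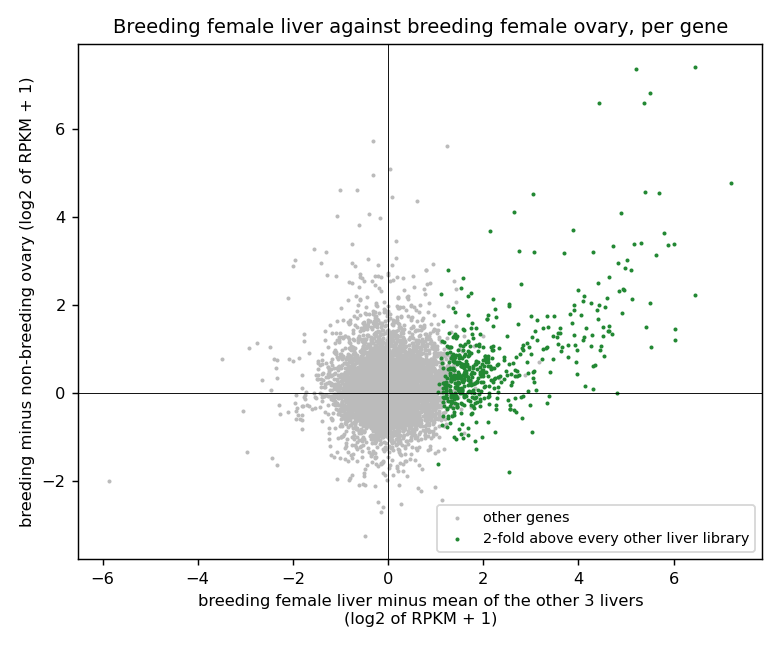
Per gene, the log2 ratio of the breeding to the non-breeding ovary (vertical) against the log2 difference of the breeding female liver from the mean of the other 3 livers (horizontal), for genes at 1 RPKM or more in liver and in ovary. The 501 genes 2-fold or more above every other liver (green) lie mostly above 0 on the vertical axis, and 148 of them are 2-fold or more higher in the breeding ovary.

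In the testis, 98 of 15452 genes were 2-fold or more higher and 408 lower in the breeding library. DMR_00791 (14.6 against 1.39 RPKM) and DMR_18067 (19.8 against 2.85) had the highest ratios, and DMR_11289 (27.95 against 265.1) and DMR_17526 (17.5 against 142.1) the lowest. The 814 genes of the testis group lay lower in the breeding testis as a set, with a median log2 ratio of -0.37 against -0.06 for all genes, below the medians of all 10000 random lists, and 75 of them were 2-fold or more lower and 4 higher. Ratios in the testis also rose with coding length (Spearman rho 0.251 across 15452 genes), against -0.109 in the ovary. Each of these values compares a library with a library and has no replicate check.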

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

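The tests of RNA from another tissue, of the library labelled brain, of liver genes in the breeding female kidney, of genes apart in both breeding female libraries and of deviations shared by a class were chosen after the results they bear on had been seen.

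The 4 genes called between breeding and non-breeding libraries of kidney, liver and brain were followed into ovary and testis, which the fit had not used. The log2 ratio had the fitted sign in 8 of 8 combinations of gene and gonad, and 7 of 8 reached 0.5 of the fitted size or more, with a median of 0.659 and a range of 0.0979 to 1.59. That argues against a response confined to kidney, liver and brain, and is consistent with a difference carried by all libraries of the breeding classes. Scaling does not account for the 3 genes that rose, whose largest adjusted p under 3 other scalings was 0.00461. For the gene that fell, the size of the difference does not come from scaling: it was -0.93 (SE 0.117) as deposited, -0.93 (adjusted p = 0.0302) with trimmed means, -0.97 (adjusted p = 0.00903) with quantile normalization and -0.89 (SE 0.131, adjusted p = 0.0757) after scaling to reads on genes. The call ended under the last through a wider spread and a slightly smaller difference, so whether it holds is left open. Breeding status, age, descent of the animals and a shared handling of their samples may each mark a class in every tissue and were not tested.

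Chance cannot be excluded for the number of these calls. Among 100 splits of the 12 libraries, 5 gave as many genes as the real split with its 4, the real one included, and the highest of the others gave 12. For the sexes, 1 of 100 splits, the real one, gave 78 genes or more and the highest other gave 57. The other splits were drawn without regard to tissue and left the sex difference in their residual, which can lower their counts. The real split is balanced within each tissue, so this share alone cannot exclude chance for the number of sex calls. These splits break up the classes of status and sex, whose libraries mostly deviated together across tissues (median Spearman rho 0.253 across genes), so a shared difference between animals is not excluded. Among 100 labellings of the 16 libraries by tissue, 1 gave the 3464 genes higher in brain (highest other 934) and 1 the 2661 genes higher in liver (highest other 251). For kidney it was 2, with 2153 genes under the real labelling and 3228 under the highest other. That labelling happened to place the kidney label on all 4 brain libraries and so follows a structure of the samples. In brain, liver and kidney the share lay under the bound of 5 in 100 set before, which argues against tissue labels that fell at random. Shuffled labels left the tissue differences in the residual, which lowers their counts. The shares therefore do not measure how many of the tissue calls could be wrong.

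The breeding female liver stood apart from the other 3 livers. It had 772 genes 2-fold or more above or below all of them, where the others had 69 to 183, and 685 of the 772 lay above. The breeding female kidney had 392 such genes, against 66 to 141 in the other kidneys, and 272 of the 392 lay below. A trend with coding length is argued against by Spearman rho values across genes of 0.0526 in kidney and -0.00842 in liver. RNA quality was examined through this trend alone, so effects of quality without such a trend stay open. RNA from another of the sampled tissues is argued against too. The 10 most abundant genes of each of these stood at a median of no more than 1.05% of their level at home. Cells or tissues that were not sampled could not be examined, since identifiers carry no names. The ovary group lay above all genes in both libraries, by a median of 0.30 (log2, 28 genes) in liver and 0.27 (36 genes) in kidney, more than any other group. A property of the class seen in liver and kidney alike is argued against as the whole cause by a Spearman rho of 0.0398 across genes between the 2 libraries, where the other 3 classes had 0.201 to 0.427. Genes apart in both libraries numbered 6 above, where independent lists would share 4.03, and 5 below, against 1.48, while the other classes shared 1 to 13, against 0.0309 to 0.562. A share in part stays open for the genes above in liver. Of the 685 genes above in liver, 411 were measured in kidney, where their median log2 ratio of the breeding to the non-breeding female was 0.28, above all random lists, and 11.2% were 2-fold or more higher against 5.25% of all genes. The state of these animals, including breeding, and handling of single samples stay open as well.

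Brain ratios ran opposite in the sexes, with r = -0.288 across 14343 genes. A trend with coding length was present, with Spearman rho of -0.226 for the male and 0.249 for the female ratio. Taking off the median of each of 50 bins of coding length left r at -0.253, with 17 genes 2-fold or more in the same and 60 in opposite directions, so this trend does not carry the pattern. The library labelled brain is not the one that stands out: 46 genes lay 2-fold outside the other 3 brain libraries, against 115 for the breeding male. A response of opposite direction in the sexes, other dissections of the brain, and differences between animals may each underlie it, and with 1 library per group they were not tested.

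Among 33 sets of 4 libraries examined, 4 had a library far from the rest by Dixon's criterion for 4 values, where chance flags about 1 in 20. The count of 772 genes in the breeding female liver was one. DMR_10289, the leading liver gene, stood at 425.6 RPKM in the non-breeding male kidney and at 18.4 to 77.1 in the other kidneys. DMR_07783, the leading kidney gene, stood at 5.28 RPKM in the breeding male liver and at 1.11 to 1.52 in the other livers. DMR_17735, the leading brain gene, stood at 1.545 RPKM in the non-breeding male liver and at 0.122 to 0.232 in the others.

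The breeding effect on DMR_05374 differed between tissues. The difference of effects was -4.41 (log2, SE 0.315, limma adjusted p = 0.0267) for brain against liver and -4.41 for kidney against liver. The gene was listed at 0 in all 8 brain and kidney libraries, so both values restate the liver difference. Those libraries add no spread to the estimate behind the p-value, and each non-breeding liver held 1 read of the gene. In testis it stood at 193.8 RPKM in the breeding and 753.8 in the non-breeding library.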

How the results depend on the processing

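The tests with scaling to reads on genes, with voom and without the breeding female liver and kidney were chosen after the data were seen. Trimmed mean scaling left all 28 counts within 1.5 times, and class as a fixed block all 10 tissue counts. The cause of the changes below was not tested unless stated.

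With a pseudocount of 0.1 the liver calls for breeding went from 2 to 0 and both calls for a breeding effect that differs from that in liver from 1 to 0. Genes moving the same way in both sexes became 51 in brain, 211 in kidney and 279 in liver, genes lower in the breeding ovary 476, and genes higher and lower in the breeding testis 275 and 724. With a 4-fold threshold, which by construction keeps fewer genes, these counts were 2, 6 and 9, then 20 (185 higher) in ovary and 4 and 19 in testis. Without a filter the shared sex count was 31 and the liver breeding count 1. Quantile normalization took both calls for a differing breeding effect to 0. Array weights gave 547 genes for sex and 25 for sex in kidney.

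Scaling to reads on genes gave 1229 genes higher and 9058 lower in liver, 2984 higher in ovary, 2071 lower in testis, 28 for sex, 22 for sex in liver and 1 for breeding in liver. The cause for the tissue counts is the construction: the median gene moved by -0.80 (log2) in liver. Voom gave 1459 and 10787 in liver, 3948 higher in ovary, 6716 and 1958 in testis, 215 for sex, 26 for sex in kidney, 61 for sex in liver, 1 for breeding in kidney and 0 for a breeding effect differing between liver and either brain or kidney. Class as a random block (consensus correlation -0.0981) gave 12 for breeding and 765 for sex. With status and sex in the model, the classes leave little to estimate this correlation from. A negative value narrows the error of comparisons between classes, so the larger counts do not strengthen the calls.

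Without the library labelled brain the shared sex count was 14, and the counts within brain, kidney and liver for sex, in liver for breeding and for differing effects were all 0. With kidney and liver only, 2 genes were called for breeding, 8 for sex, 7 for sex in kidney, 20 for sex in liver and 0 for a differing effect. Both fits have fewer libraries. Without the breeding female liver and kidney the breeding count was 4 and the sex count 379.

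Leaving out each library in turn gave 3 to 57 genes for breeding (57 without the breeding female brain) and 9 to 749 for sex. For sex the count was 749 without the breeding female liver, 35 without the breeding female kidney and 12 without the breeding female brain. It was 9, 14 and 14 without the breeding male liver, kidney and brain, 12 and 9 without the non-breeding female liver and kidney, and 11 and 14 without the non-breeding male kidney and brain. Within tissues the range was 0 to 7 for sex in brain, 0 to 10 for sex in kidney, 0 to 227 for sex in liver and 0 to 247 for breeding in liver. Effects differing between brain and liver numbered 0 to 119, and between kidney and liver 0 to 128. The breeding count in liver was 231 without the breeding male and 247 without the non-breeding male liver, and the sex count 227 and 224 without the non-breeding female and male livers. By construction such a fit has no residual in liver and assumes that liver varies like brain and kidney. No tissue count moved by over 1.5 times. The gene list alternatives were not run, since identifiers carry no names.

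No gene named in a fitted comparison changed sign under the alternatives run for it. The ovary and testis ratios of single genes were not recomputed. Depth limits low genes: a count of 0 in a library allows up to 3 reads.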

Other observations

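All tests in this part were chosen after the data were seen. Some genes that stood high in the breeding female liver were also higher in the breeding than in the non-breeding ovary. Of the 685 genes 2-fold or more above every other liver, 501 were measured in ovary, and 148 of these (29.5%) were 2-fold or more higher in the breeding than in the non-breeding ovary, against 6.35% of all genes, while 7 were lower. Their median log2 ratio was 0.54, above the medians of all 10000 random lists. In kidney the median of 411 such genes was 0.28, also above all random lists, and 11.2% were 2-fold or more higher, against 5.25% of all genes. In brain the median of 375 genes was 0.00, at percentile 56.8, and 6.4% were 2-fold or more higher, against 1.6% of all genes. Of the 87 genes 2-fold or more below every other liver, 61 were measured in ovary, with a median of 0.03 (percentile 44.65), and 13.1% of them were 2-fold or more higher there. The 5 genes with the highest ovary ratios, 125- to 203-fold, were all among the 685, at 2482 to 15770 RPKM in the breeding female liver and 15.2- to 49-fold above the next liver. DMR_07981 stood at 15770 RPKM in that liver, at 62.8 to 322 in the other livers and at 65.4 to 201 in the kidneys. The 10 most abundant liver genes stood in the breeding ovary at a median of 0.0194% of their liver level.

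Of the 20 most abundant liver genes, 17 were above the mean of the other kidneys in the non-breeding male kidney, by a median of 0.278% of their liver level and within 2-fold of that median for 12. In the other 3 kidneys 3 to 6 of the 20 were above. In the non-breeding male kidney 32 of the 298 liver genes were 2-fold or more above each other kidney, against 1 to 5 for the remaining libraries.

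Brain genes lay lower in the breeding than in the non-breeding male brain, with a median log2 ratio of -0.25 for 751 genes, below the medians of all 10000 random lists, and 32 of them were 2-fold or more lower and 4 higher. The median of all genes in that pair was -0.03, and 256 testis genes lay at -0.20, also below all random lists. Kidney genes lay at 0.00 (percentile 37.6), liver genes at 0.03 (63.8) and ovary genes at 0.10 (80.9). Ratios of that pair fell with coding length (Spearman rho -0.216 across 14578 genes), and the breeding male brain had 115 genes 2-fold outside the other brains. In the female pair the median of the 751 genes was -0.03, at percentile 27.7. Libraries of the same status and sex mostly deviated together across tissues. Across genes, the deviations from the tissue mean correlated between tissues with a median Spearman rho of 0.253 over 12 pairs of the same class, 10 of them above 0.1. The exceptions were both of the breeding female liver, with -0.116 to the brain and 0.0398 to the kidney of its class. The median was -0.0816 over 36 pairs of different classes, which deviations from a mean of 4 push below 0 by construction. Of these 36 pairs, 7 were also above 0.1, the highest at 0.268. The deviations were not corrected for coding length. Spearman rho with coding length was -0.204, -0.141 and -0.165 in the breeding male brain, kidney and liver. It was -0.109, 0.167 and 0.164 in those of the non-breeding female, and of mixed sign in both other classes. What such trends add to the shared deviations was not tested. Which libraries share an animal is not given in the labels.

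The 8 genes read in males and nearly absent from females had 2 pairs of consecutive identifiers among them, where 10000 random draws of 8 tested genes had at most 1 (p = 0.0001, the smallest these draws can give, 1-sided permutation test). How identifiers were numbered is not given in the sources used here.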
